A study of Mus musculus with 3 samples.

How the data were processed

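Gene expression was measured in glomeruli isolated from the kidneys of nondiabetic male FVB/NJ mice aged 8 weeks, with 1 Affymetrix mouse whole-genome expression array for each of 3 mice. This array carries sets of short oligonucleotide probes, and each probe set reads the 3′ part of a transcript. Per the labels' protocols, RNA came from a pool of isolated glomeruli of each mouse, was treated with DNase, and was amplified and biotin-labelled from its 3′ end. The submitters reported high RNA integrity scores for all samples in the same protocols. The replicate numbers 1 to 3 come from the sample titles, and the mice are named mouse 1, mouse 2 and mouse 3.

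The series was set up to compare diabetic OVE26 mice with nondiabetic FVB mice. Only the FVB arrays were used, and OVE26 mice were not analysed here, so no comparison between groups was made. All statements concern the level of expression in FVB glomeruli and the spread between the 3 mice.

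The deposited values were read as log2 expression values. Per the submitters' processing notes the arrays were summarised with GCRMA, whose version is not given in the sources used here. GCRMA corrects for background by probe sequence, normalises the arrays to a common distribution and reports 1 value per probe set. The log2 scale was inferred from the values, which ran from 0.67 to 14.76, and it is not stated in the labels. Which arrays were normalised together is also not given in the sources used here. GCRMA sets many dim probe sets to nearly the same low value, and some probe sets have identical values on a pair of arrays (2.18% to 2.49% of probe sets per pair), which lowers their SD. Such ties were not limited to dim probe sets, as Lamb2 was at 9.62 in both mouse 1 and mouse 3. No further normalisation was applied.

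Probe sets were named through the platform annotation supplied for this array. Of 45101 probe sets, 64 were control probe sets, 34958 had 1 gene symbol, 932 had several and 9211 had no gene listed there. Of the probe sets with 1 gene, 34754 had a gene identifier that matched the reference gene table (assembly GRCm38.p6), and no symbol needed an update. Probe sets with several genes were not used for any gene. Where a gene had several probe sets (9012 of 18194 genes), the one with the highest mean over the 3 arrays stood for it. No coordinates are given, since the sources used here name no genome build for these arrays. There were 0 columns of per-sample values left unused.

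Background was set on each array as the 95th percentile of 80 probe sets for olfactory and vomeronasal receptors, which serve here as an empirical floor. The thresholds were 2.58, 2.91 and 2.86 on the log2 scale for mice 1, 2 and 3. A gene was tested when its probe set exceeded the threshold on all 3 arrays. Signal over this floor, and the number of arrays, limit the precision of every value.

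The SD over the 3 mice was taken per gene on the log2 scale. Excess variance between mice was tested with limma, by setting each gene's variance against the scaled F distribution fitted across all tested genes, with a trend on mean level and a robust fit. P-values are one-sided for the upper tail and were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. A 2-fold range means that the highest and the lowest mouse differed by at least 1 on the log2 scale.

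Gene lists of 321 genes were fixed before the data were examined, as were the tests, the rule for named genes and most of the alternative settings. The cell type lists were podocyte, glomerular endothelium, mesangium and pericyte, arteriolar smooth muscle, parietal epithelium, proximal tubule, loop, distal and collecting duct, macrophage and antigen presentation, lymphocyte and granulocyte, erythroid and adipocyte. The other lists were glomerular basement membrane and matrix, fibrosis and inflammation, renin-angiotensin, glucose handling and insulin signalling, oxidative stress and metallothionein, immediate early, heat shock, circadian clock, interferon response, proliferation and oxidative phosphorylation. A list entered the comparison of mice when it had at least 4 tested genes, which left 19 lists. The median SD of a list, and for each mouse the median difference between that mouse and the mean of the other mice, were placed among 10000 random lists of the same size matched on mean level in 20 bins. A list had high spread at or above the 97.5th percentile, and a mouse stood apart at or beyond the 2.5th or 97.5th percentile. After the data were seen, a stricter reference was added, in which the values of each gene were shuffled among the mice 10000 times, so that each gene kept its own spread. The 3 differences of a list sum to about 0 and are not independent, and genes of a list are not independent replicates. The percentiles describe these arrays and are not p-values.

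The named genes are the first 2 members of every list with a probe set of 1 gene, the 10 genes with the largest SD, the 4 members with the largest SD in each list of high spread, list members not above background, and sex-linked genes as a check of the male label. Up to 10 genes passing the variance test would have been added, but none passed. Genes of lists written later, used in the closing section, were chosen outside this rule, as was Ifi27l2a.

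Both procedures were tested on simulated data for 10610 genes. With the spread of variances fitted here (3.11 prior degrees of freedom), the variance test found 0 of 200 genes whose SD was multiplied by 5, and 83 of 200 whose SD was multiplied by 20, with 4 false calls. With 20 prior degrees of freedom it found 111 and 197 of 200. Lists with one mouse shifted by 0.5 on the log2 scale were found in 92.2% of 180 cases by random lists and in 70.6% by shuffling, when each gene kept its own SD. Lists with no shift were then called in 30% and 6.11% of 180 cases, against 3.33% and 5% when SDs were drawn from the fitted distribution, so list differences are described first by the shuffled reference. The simulated genes were independent of each other, so these shares do not cover lists whose genes move together.

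Alternatives were a higher percentile and another silent gene set for the background, no filter on dim genes, quantile normalisation, centring of each array, the mean over the probe sets of a gene, leaving out probe sets prone to cross-hybridisation, leaving out each mouse, other forms of the variance fit and a larger range. Calculations used R 4.3.3 with limma 3.58.1 and matrixStats 1.5.0, and plots used matplotlib 3.10.9.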

Results

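The data describe the glomerular transcriptome of 3 nondiabetic male FVB/NJ mice aged 8 weeks, an inbred strain that serves as the control of the diabetic OVE26 line. Expression was measured with 1 array per mouse (n = 3). Values are log2 GCRMA expression values, and errors are SD over the 3 mice. The arrays had similar medians, at 2.82, 2.85 and 2.82 for mice 1, 2 and 3, which normalisation to a common distribution brings about. Above background lay 24578, 22095 and 22319 probe sets. The threshold was lowest for mouse 1 (2.58, against 2.91 and 2.86), so its higher count does not show that more genes were expressed. Of 18194 genes, 10610 (58.3%) were above background in all 3 mice, 6429 were below it in all 3 and 1155 gave mixed calls. Across genes above background, which are not independent replicates, Pearson's r was 0.988 between mice 1 and 2, 0.984 between mice 1 and 3 and 0.985 between mice 2 and 3. The Y-linked genes Eif2s3y (8.47 ± 0.21), Kdm5d (7.64 ± 0.15) and Uty (7.30 ± 0.09) were above background in all mice, and Xist, which is transcribed from the inactive X chromosome, was below it in all (2.07 ± 0.11), as the male label implies.

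The first question was which genes of the resident glomerular cells were measured, and how closely the mice matched. All 17 podocyte genes with a probe set were above background in all mice. Nphs1, which encodes nephrin of the slit diaphragm, was at 11.19 ± 0.25, and Podxl, which encodes the podocyte sialoprotein podocalyxin, was at 14.54 ± 0.03. The latter lies just under the highest values of the arrays (14.66 to 14.76), where differences may be compressed, and the other probe set of Podxl was at 11.64, 11.18 and 11.35 in mice 1, 2 and 3. Their median SD was 0.0806, inside the 0.0673 to 0.153 of the middle 95% of random lists of like level, and 1 of the 17 had a 2-fold range. Glomerular endothelial genes were above background for 17 of 18 members, among them the VEGF receptor gene Kdr (12.48 ± 0.11) and Ehd3 (13.30 ± 0.05), with a median SD of 0.132 and no 2-fold range. Of 12 mesangial and pericyte genes 10 were above background, with Pdgfrb, a receptor of platelet-derived growth factor, at 13.27 ± 0.07, Itga8 at 13.38 ± 0.12 and a median SD of 0.136. All 16 genes of the glomerular basement membrane and matrix were measured, with a median SD of 0.135. They include the type IV collagen gene Col4a3 (11.67 ± 0.13) and the laminin gene Lamb2 (9.69 ± 0.12). Parietal epithelial genes were above background for 3 of 6 members, with Cldn1 at 8.01 ± 0.20 and Pax8 at 3.59 ± 0.23.

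Small differences between mice were present within these lists. Endothelial genes were higher in mouse 1 than in the other mice by a median of 0.17, with 12 of 17 genes highest there, and matrix genes were higher in mouse 2 by 0.18, with 11 of 16 highest there. The contractile genes of arteriolar smooth muscle, 6 of 8 of which were above background, were lower in mouse 3 by a median of −0.32, and 5 of 6 were lowest there. Acta2 (10.49 ± 0.42), the smooth muscle actin gene, and Myh11 (6.96, 7.33 and 6.69 in mice 1, 2 and 3) belong to this list, whose median SD of 0.242 lay inside the random range. These 3 differences lay beyond the tails of both the random lists and the shuffled values. With the mean over the probe sets of each gene, the endothelial median in mouse 1 was 0.15 and lay inside the tails of the random lists. Markers of other cell types differed in the same mice, with medians of −1.86 for proximal tubule and 1.57 for lymphocyte and granulocyte genes in mouse 1, 0.82 for loop, distal and collecting duct genes in mouse 2 and 2.43 for proximal tubule genes in mouse 3. The array of mouse 2 also had the highest value for all 18 bacterial and phage control probe sets, by a median of 0.54. Podocyte genes did not stand apart in any mouse, with median differences of 0.04, 0.03 and −0.04.

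Genes of the tubule, which surrounds the glomerulus in the cortex, differed far more between the isolates. Of 18 proximal tubule genes, 17 were above background in all mice, 15 had a 2-fold range, and all 17 were highest in mouse 3. Their median lay 2.43 above the mean of the other mice there, a 5.39-fold difference, and −1.86 in mouse 1, where 14 of 17 were lowest. The sodium-phosphate cotransporter gene Slc34a1 was at 4.44, 5.35 and 7.41 in mice 1, 2 and 3, and the megalin gene Lrp2 was at 5.04, 5.43 and 7.81. The inositol oxygenase gene Miox (4.20, 5.48 and 8.52), Cyp2e1 (6.15, 6.01 and 9.60), Slc13a3 (4.63, 5.78 and 8.55) and Slc7a13 (2.87, 3.45 and 6.60) had the largest SDs of the list. The median SD was 1.4995, against 0.112 to 0.265 in random lists. The actin 3′ minus 5′ control difference, a sign of RNA quality, also rose from mouse 1 to mouse 3 (1.49, 1.81 and 2.05). That of Gapdh was highest in mouse 2 (0.48, 1.08 and 0.92).

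Genes of the loop, distal tubule and collecting duct gave a different order of the mice. Of 14 genes 8 were above background in all mice, and 7 of these 8 were lowest in mouse 1 (median −0.82) and 7 were highest in mouse 2 (median 0.82, or 1.76-fold). In mouse 3 the median was −0.05. Slc12a3, Aqp2, Aqp3, Scnn1b, Fxyd4 and Hsd11b2 were not above background in all mice and did not enter these medians. With Aqp2, Aqp3 and Fxyd4 left out, the medians say little on the collecting duct. Umod, which encodes uromodulin of the thick ascending limb, was at 12.47, 13.56 and 13.06 in mice 1, 2 and 3. The furosemide-sensitive cotransporter gene Slc12a1 was at 10.09, 11.68 and 10.85, the potassium channel gene Kcnj1 at 6.36, 8.67 and 7.52, and Cldn16 at 3.92, 6.32 and 4.47. Calb1 was the exception, with its highest value in mouse 3 (3.80, 3.64 and 5.55). The median SD of the list was 0.671. On the array of mouse 2, all 18 bacterial and phage control probe sets were highest too (median 0.54). The actin and Gapdh 3′ minus 5′ control differences were lowest in mouse 1 (1.49 and 0.48).

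Leukocyte genes were highest in mouse 1 in most cases, and the MHC class II genes H2-Aa and H2-Ab1 were highest in mouse 3. Of 15 genes of the macrophage and antigen presentation list, 8 were above background in all mice, 6 had a 2-fold range and 5 were highest in mouse 1, with a median SD of 1.02. The adaptor gene Tyrobp was at 6.78, 4.79 and 3.36 in mice 1, 2 and 3, and the lysozyme gene Lyz2 at 9.47, 8.22 and 7.02. H2-Aa was at 6.45, 4.61 and 7.04 and H2-Ab1 at 4.44, 3.33 and 5.87, while Cd74, the invariant chain of MHC class II, was highest in mouse 1 (4.59, 3.88 and 4.43). The median of the list in mouse 1 was 0.82, inside the tails of the shuffled values. Of 13 lymphocyte and granulocyte genes only 4 were above background in all mice, with a median in mouse 1 of 1.57 and a median SD of 1.03. They were the pan-leukocyte phosphatase gene Ptprc (7.43, 6.58 and 5.13), S100a8 (6.79, 5.19 and 4.28), S100a9 (4.94, 3.31 and 3.46) and Ighm (3.63, 3.91 and 3.62). The T cell gene Cd3e was below background. Without mouse 1, or with no filter on dim genes, the spread of this list was no longer high, and with no filter its median in mouse 1 was 0.19.

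Marker genes of blood and fat were measured in part. Of 5 erythroid genes with a probe set 3 were above background in all mice, with means of 3.21 to 5.56. The globin gene Hba-a1 was below background in all mice and Hba-a2 was above it in 2 of 3. Each was read by 1 probe set, and probe sets of several genes were not used. These values therefore do not show that globin RNA was absent. Of 6 adipocyte genes only Fabp4 (11.46 ± 0.39), which encodes a fatty acid binding protein, was above background. The other 5, Adipoq among them, were below it in all mice, so Fabp4 alone does not show fat in the isolates.

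Interferon-responsive genes separated mouse 3 from the others. Of 12 genes with a probe set 11 were above background, 7 had a 2-fold range and 10 of 11 were highest in mouse 3, where the median difference was 1.11 (2.16-fold). In mouse 2 the median was −0.72 and 9 of 11 were lowest. The guanylate binding protein gene Gbp2 was at 9.26, 8.45 and 12.78 in mice 1, 2 and 3, Ifit1 at 6.69, 5.77 and 8.19, Ifit3 at 8.15, 6.82 and 9.13, and Oasl2 at 6.96, 6.48 and 8.32. The transcription factor gene Irf7 was at 3.57 ± 0.67. Ifi27l2a, also with a 2-fold range, went the other way and was lowest in mouse 3 (5.76, 5.70 and 4.45). The median SD of the list was 0.671, against 0.0966 to 0.279 in random lists. Proximal tubule genes were also highest in mouse 3 (median 2.43). In mouse 2 loop, distal and collecting duct genes were higher (0.82), and all 18 bacterial and phage control probe sets were highest there (0.54).

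Heat shock and immediate early genes were lowest in mouse 1. All 12 heat shock genes were measured, 9 were lowest in mouse 1, and the median there was −0.74 (1.67-fold), with a median SD of 0.434. The inducible HSP70 genes Hspa1a (5.21, 10.51 and 11.13) and Hspa1b (9.79, 12.96 and 13.36) had ranges of 60.4-fold and 11.9-fold. They are near-identical copies, so their probe sets may share signal. Hsph1 was at 9.81, 11.35 and 11.80, and the HSP40 gene Dnajb1 at 9.49, 11.31 and 10.37. Of 20 immediate early genes 16 were above background and 11 of these were lowest in mouse 1, with a median of −0.35 there and a median SD of 0.300. Fos was at 8.75, 10.10 and 10.09 in mice 1, 2 and 3, Egr1 at 8.43, 9.54 and 9.21, Gadd45b at 7.32, 8.14 and 8.72, and Atf3 at 3.09, 4.16 and 3.99. Nr4a1 was highest in mouse 2 (8.04, 10.36 and 7.79). Tubule genes were also lowest in mouse 1, with medians of −1.86 for the proximal and −0.82 for the distal list, and lymphocyte and granulocyte genes were higher there (1.57). The 3′ minus 5′ difference of the control probe sets, a sign of RNA quality, was also lowest in mouse 1 for actin (1.49, 1.81 and 2.05) and for Gapdh (0.48, 1.08 and 0.92).

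Circadian clock genes varied between mice, and the direction differed within the list. Of 16 genes 14 were above background and 6 had a 2-fold range, and the median SD was 0.318, against 0.0917 to 0.232 in random lists. Arntl, which encodes the activator BMAL1, was lowest in mouse 1 (3.16, 4.91 and 4.09), where the clock output gene Dbp was highest (12.94, 12.41 and 12.44). Per2 (8.25, 7.22 and 9.25), Cry1 (8.65, 7.12 and 8.86) and Nfil3 (3.33, 4.05 and 5.41) were highest in mouse 3. For Per2 the 3 probe sets above background differed in which mouse was highest. No mouse stood apart for this list by shuffling, but a list median cancels opposite differences such as those of Arntl and Dbp. A shift in clock phase could therefore not be seen this way. In mouse 1, 6 of 14 genes were highest and 4 lowest, and in mouse 2, 4 were highest and 7 lowest. Without mouse 2 the spread of the list was no longer high.

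Lists related to diabetic kidney injury gave a baseline for these control mice. Of 14 fibrosis and inflammation genes 7 were above background, with a median SD of 0.397. Tgfb1 was at 5.56 ± 0.61, the connective tissue growth factor gene Ccn2 at 14.13 ± 0.03, the adhesion gene Icam1 at 7.84 ± 0.61, Thbs1 at 6.73 ± 0.55 and Col3a1 at 5.45 ± 0.40. Without mouse 1, or with no filter on dim genes, the spread of this list was no longer high. Of 7 renin-angiotensin genes 4 were above background, with Ace at 3.66 ± 0.01, Agt below background and a median SD of 0.0797. The value of Ace was identical in mice 1 and 3 (3.65), a tie that lowers its SD. Glucose handling and insulin signalling genes were above background for 11 of 13 members, with the insulin receptor gene Insr at 9.97 ± 0.51, the glucose transporter gene Slc2a1 at 9.77 ± 0.31 and a median SD of 0.162. For oxidative stress and metallothionein genes, 13 of 15 were above background and the median SD was 0.189. The NADPH oxidase gene Nox4 was at 5.10, 6.94 and 7.68 in mice 1, 2 and 3, the order in which Slc34a1 and Lrp2 also lay, and the superoxide dismutase gene Sod2 at 10.66 ± 0.19.

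All 17 oxidative phosphorylation genes were measured with a median SD of 0.0979, including Ndufa4 (11.29 ± 0.09) and Cox5a (12.49 ± 0.10). They were higher in mouse 2 by a median of 0.13, with 13 of 17 highest there, as were 7 of 8 loop, distal and collecting duct genes (median 0.82) and all 18 bacterial and phage control probe sets (median 0.54). In mouse 3 they were lower by a median of −0.12, with 12 of 17 lowest there, which stood apart by shuffling and not by random lists. Of 15 proliferation genes 7 were above background in all mice, with a median SD of 0.218, and 6 of 7 were highest in mouse 1 (median 0.31), where lymphocyte and granulocyte genes had a median of 1.57. With the mean over the probe sets of each gene, the proliferation median was 0.12 and lay inside the tails of the random lists. Mki67 was above background in 2 mice and Top2a in 1.

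**Figure D1:**
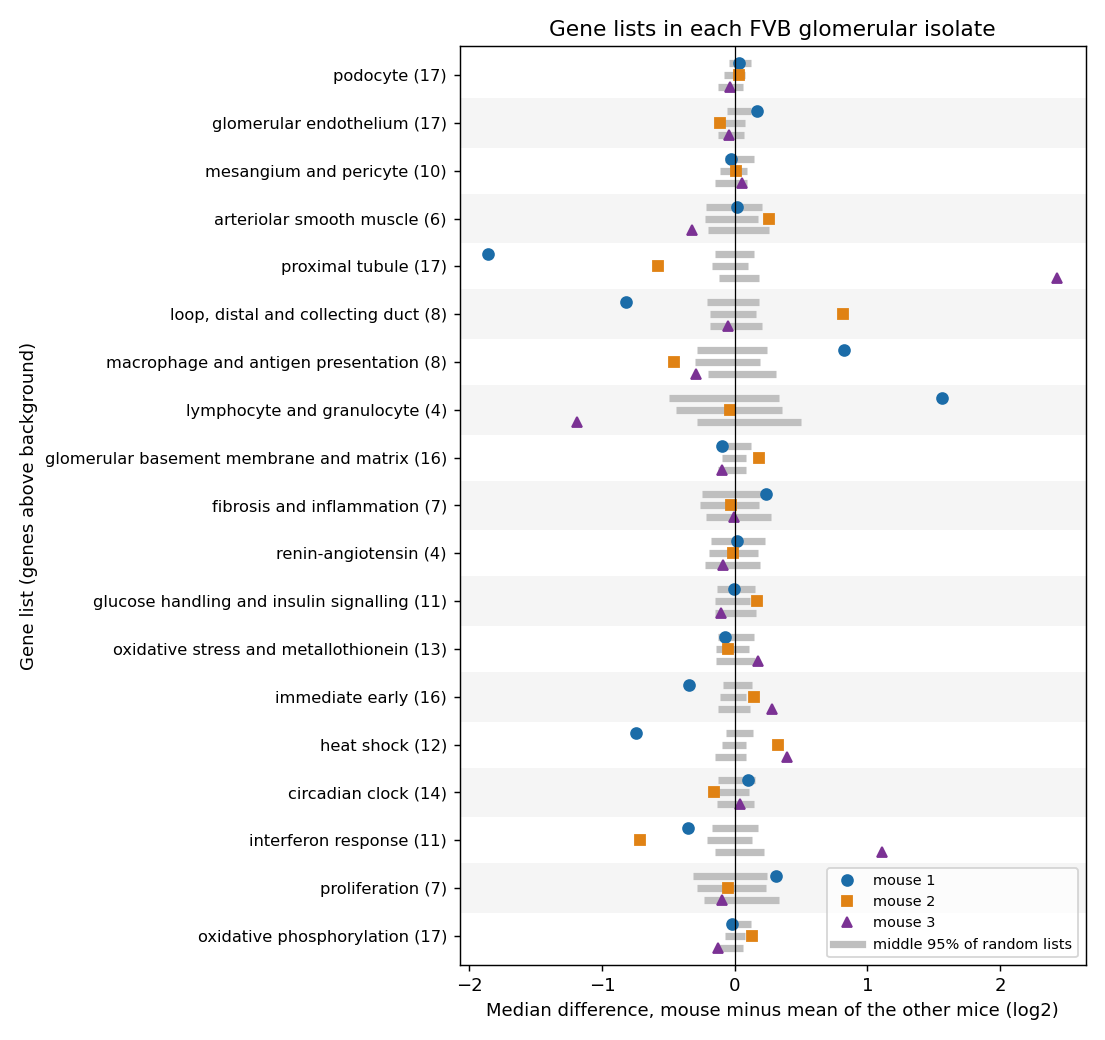
Median difference on the log2 scale between each mouse and the mean of the other mice for the 19 gene lists with at least 4 genes above background, with the number of such genes in parentheses. Points are the 3 mice and grey bars are the middle 95% of 10000 random lists of like level. Proximal tubule genes reach 2.43 in mouse 3 and −1.86 in mouse 1, and the podocyte points lie inside their bars.

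Over the 19 lists, 9 had high spread. By shuffling within genes 15 of 57 pairs of list and mouse stood apart, where the false calls on simulated data with each gene's own SD would give 3.48. By random lists 31 pairs did, where such false calls would give 17.1. The simulated genes were drawn independently, while genes of a list can move together. False calls may thus be more frequent here, and the excess over 3.48 and 17.1 is not evidence by itself. By both references 14 pairs stood apart. All 14 stayed in the tails of the random lists after quantile normalisation and after centring of the arrays, which both changed the values little (612 and 632 genes with a 2-fold range, against 630).

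The 10 genes with the largest SD over the mice included a heat shock gene, a proximal tubule gene and several interferon-inducible genes. Zbtb16, a zinc finger transcription factor gene, had the widest range at 80.5-fold (6.64, 4.54 and 10.87 in mice 1, 2 and 3), and each of its 3 probe sets was highest in mouse 3. Genes of interferon-inducible GTPases were Gbp6 (5.51, 4.49 and 10.39), Gbp2, Igtp (8.24, 7.50 and 11.86) and Gm4951 (6.77, 5.45 and 9.89), and probe sets of this family may cross-hybridise. Cd274, which encodes the checkpoint ligand PD-L1, was at 3.91, 3.20 and 8.98, and Nlrc5, an activator of MHC class I genes, at 4.53, 2.97 and 8.18. Cyp26b1, which encodes an enzyme that degrades retinoic acid, was lowest in mouse 2 (12.37, 7.79 and 11.67), a 23.9-fold range. Hspa1a and Miox complete the set. Proximal tubule genes were highest in mouse 3 as well (median 2.43). Among the 82 genes named by list order, by SD or as sex-linked genes, 12 had a 2-fold range and more than 1 probe set above background. For 11 of these all such probe sets were highest in the same mouse.

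**Figure D2:**
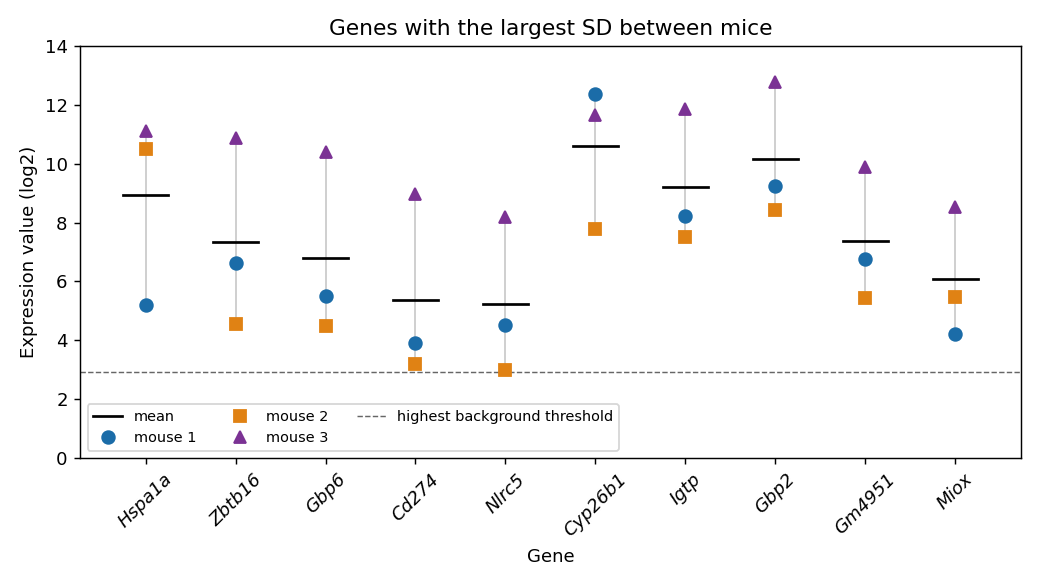
Log2 expression values of the 10 genes with the largest SD between mice. Points are the 3 mice, black lines are means, grey lines join the lowest and highest mouse, and the dashed line is the highest background threshold (2.91). In 8 of the genes other than Cyp26b1 and Hspa1a, mouse 3 lies well above the other mice, as for Cd274 at 8.98 against 3.91 and 3.20.

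Across all 10610 genes above background the median SD was 0.157, with an interquartile range of 0.0904 to 0.260. The median SD was 0.226 in the lowest tercile of mean level and 0.114 in the highest tercile. A 2-fold range was present for 630 genes (5.94%), of which 325 were highest in mouse 3, 187 in mouse 2 and 118 in mouse 1. It was present for 320, 371 and 319 genes without mouse 1, 2 and 3, where the range is taken over fewer mice. No gene passed the limma variance test, with a smallest adjusted p of 0.469. No gene named above therefore passed a test of its spread between mice. In that test 494 genes (4.66%) had an unadjusted p under 0.05. The reference distribution was fitted to the variances of these same genes, so a share near 5% is set by the fit. It says nothing on whether the spread between mice was large. On simulated data of this kind the test found 0 of 200 genes whose SD was multiplied by 5.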

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

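The list spread without each mouse and the shuffled reference were chosen after the data were seen. Genes above background in all mice numbered 9409 to 10822 over the alternatives, and the median SD was 0.120 to 0.160. The limma variance test found 0 genes under all 12 alternatives, with 301 to 656 at an unadjusted p under 0.05. The count of genes with a 2-fold range was 319 to 371 when each mouse was left out, against 630, because a range over fewer mice is smaller. It was 266 for a range of at least 1.5 on the log2 scale, 431 with the mean over the probe sets of a gene and 766 with no filter on dim genes. Lists with high spread numbered 7 to 10. Without mouse 3 the glomerular endothelium joined them, and the proximal tubule list stayed high without any of the mice. Pairs of list and mouse that stood apart numbered 25 to 32 under the settings fixed earlier and 15 by shuffling, which keeps each gene's own spread. Of the 14 pairs apart by both references, 11 of 13 stayed in the tails with the mean over probe sets (not endothelium, 0.15, and proliferation, 0.12, in mouse 1), and all that could be computed did so under the other settings. List differences stayed within their spread in 88 cases and moved further in 7, gene levels did so in 776 and 42, and none of the list differences changed sign. The lymphocyte and granulocyte list had too few genes above background in 3 settings. Signal over background limits genes near the threshold, and 3 arrays limit every SD.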

Other observations

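Tests chosen only after the result was seen were the order of mice 1 and 2, the heat shock list without the HSP70 genes and the 3′ to 5′ control differences. All lists added in this section were written after the data were first seen. Those of glucocorticoid-responsive, retinoic acid-responsive and MHC class I presentation genes were also written after the most variable genes were known.

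Glucocorticoid-responsive genes were examined because Zbtb16 had the widest range. Of 12 genes above background 8 were highest in mouse 3 and 7 were lowest in mouse 1, with medians of 0.61 and −0.60. The median in mouse 2 was −0.03. By its medians the list ordered the mice as the proximal tubule list did, whose medians were −1.86, −0.58 and 2.43 in mice 1, 2 and 3. The actin 3′ minus 5′ control difference had this order too (1.49, 1.81 and 2.05), and that of Gapdh did not (0.48, 1.08 and 0.92). Fkbp5, which encodes a cochaperone of the steroid receptor, was at 8.27, 7.75 and 10.12 in mice 1, 2 and 3, Map3k6 at 5.47, 5.27 and 7.10, and Tsc22d3, also known as GILZ, at 11.33, 11.37 and 12.02. Single genes did not all follow the order of the medians. In mouse 2, 4 of the 12 genes were lowest, Fkbp5 and Map3k6 among them, and 3 were highest. The latter include Slc10a6 (2.80, 4.95 and 4.81) and Ddit4 (6.49, 7.39 and 6.19). Retinoic acid-responsive genes were examined because of Cyp26b1. Of 7 genes above background 5 were lowest in mouse 2, with a median of −0.41, inside the tails of the shuffled values. The receptor gene Rarb was at 7.83, 6.06 and 6.56, and the transglutaminase gene Tgm2 at 10.38, 9.87 and 10.28.

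Genes of antigen presentation on MHC class I were lowest in mouse 2 for all 9 measured members (median −0.64), while 5 were highest in mouse 3 and 4 in mouse 1. The peptide transporter gene Tap1 was at 5.60, 4.13 and 8.34, and the immunoproteasome genes Psmb8 and Psmb9 were at 9.04, 7.70 and 10.56 and at 8.44, 7.21 and 10.15. This list holds Nlrc5, Tap1, Psmb8 and Psmb9, whose values were known when it was written, so it is not independent evidence. Without these 4 genes the median in mouse 3 was 0.19, against 1.05 with them, and 4 of the 5 genes left were highest in mouse 1. All 5 were lowest in mouse 2, with a median of −0.48. The class I gene H2-K1 was at 12.83, 12.33 and 12.78 in mice 1, 2 and 3. Genes of the unfolded protein response, written before their values were seen, had medians of 0.16, −0.11 and −0.02 in mice 1, 2 and 3, and that of mouse 1 stood apart upward by both references. In mouse 1 proximal tubule genes were also lower (−1.86) and lymphocyte and granulocyte genes higher (1.57). The actin and Gapdh 3′ minus 5′ control differences were lowest there (1.49 and 0.48). All 18 bacterial and phage control probe sets were highest on the array of mouse 2, by a median of 0.54.

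Proximal tubule genes were high in the isolate of mouse 3, and a candidate explanation is carry-over of proximal tubule fragments. Of 11 measured genes of a second proximal tubule list all were highest in mouse 3, with a median difference of 2.08, among them Pdzk1 (3.99, 4.46 and 6.82 in mice 1, 2 and 3) and Hao2 (5.98, 7.42 and 8.54). A second list of distal tubule and collecting duct genes had a median of 0.0845 in mouse 3, and the upper quartile of its members was 0.225. That difference is taken against a mean that includes mouse 2, where the list had a median of 1.24. All 9 distal genes were lowest in mouse 1, so they were higher in mouse 3 than in mouse 1 too. Of these 9 genes 7 were highest in mouse 2, while all 11 proximal genes were highest in mouse 3. This opposite direction between mice 2 and 3 argues against an equal carry-over of all segments in these isolates. The actin 3′ minus 5′ control difference had the order of the proximal tubule genes (1.49, 1.81 and 2.05 in mice 1, 2 and 3). That of Gapdh did not (0.48, 1.08 and 0.92), and RNA integrity was not weighed for this pattern. All mice carry the same labels, so no biological explanation was tested.

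Interferon-responsive genes were also high in mouse 3. A second leukocyte list had a median of −0.72 in mouse 3 and 0.69 in mouse 1, where all 11 genes were highest. This argues against more leukocytes in total as the source. Ptprc, Tyrobp and Lyz2 of the first lists were already lowest in mouse 3, so the second list was not a fresh test. Pan-leukocyte genes cannot show a change in leukocyte type, and H2-Aa and H2-Ab1 were highest in mouse 3. Interferon-gamma genes outside the GBP and IRG families had a median of 1.35 with all 13 highest in mouse 3, including Irf1 (8.62, 8.01 and 10.23). Cross-hybridisation within those families thus does not account for the high values outside them. Ifit1, Ifit3 and Oasl2, also outside them, were already highest in mouse 3 in the first list, so this was not a fresh test. How far cross-hybridisation adds to the ranges of Gbp2, Gbp6, Igtp and Gm4951 themselves stays open. RNA from tubule fragments stays open, since the interferon and proximal tubule lists were highest in the same mouse. Between the other mice the orders differed, with interferon genes at −0.28 for mouse 2 minus mouse 1 and proximal tubule genes at 0.91, and no biological explanation was tested.

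Heat shock genes were low in mouse 1, where the proximal tubule (−1.86) and distal (−0.82) lists were low too. Without Hspa1a and Hspa1b the median was −0.62, so signal shared between these copies does not account for the low values of the other genes. How far shared signal adds to the ranges of Hspa1a and Hspa1b themselves stays open. A second list of heat shock factor targets had a median of −0.45 in mouse 1, with 9 of 13 genes lowest there, among them Chordc1 (9.80, 10.86 and 11.18 in mice 1, 2 and 3), while the unfolded protein response list, itself higher in mouse 1, had 0.16. The heat shock factor list also had a median of 0.35 in mouse 3, with 11 of 13 highest, and −0.07 in mouse 2, the order of the proximal tubule list, so a heat shock factor programme that differs between the isolates is consistent with these values only as a hypothesis. The actin 3′ minus 5′ control difference was lowest in mouse 1 (1.49, 1.81 and 2.05), as was that of Gapdh, so RNA integrity cannot be told apart from the mouse, RNA from tubule fragments stays open as well, and no biological explanation from the design was tested.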
